A study of Homo sapiens with 2 samples.

How the data were processed

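Polyadenylated RNA was measured by RNA sequencing in 2 cultures of C4-2, an established human prostate cancer cell line derived from LNCaP that expresses the androgen receptor and grows with little androgen. One culture received vehicle and the other received ebastine, a histamine H1 receptor antagonist used against allergy. Per the labels the cells were at passage 10 to 15. They were replated, left to attach, and then received fresh medium with vehicle or ebastine. The dose and the exposure time are not given in the sources used here. Each group held 1 library, so no spread between replicates exists and no p-value of the difference between treatments was computed.

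TopHat2, Cuffdiff and the hg19 genome build are named, without versions, in the submitters' processing notes. The deposited table has the layout of a Cuffdiff gene-level comparison, with FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments) that the authors' Cuffdiff estimated and scaled between the libraries. It also holds the authors' log2 fold change of ebastine over vehicle, the authors' Cuffdiff test statistic (a score that was not used here), and the deposited p-value and q-value per gene. The gene models, the treatment of reads that map to several places, the strand setting and the scaling method are not given in the sources used here. The authors' test was made on 1 library per group, so its p-values compare these libraries and not the conditions.

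The table held 1947 genes, all with a deposited p-value under 0.05 (0.0499 at most). The deposited q-values followed a Benjamini-Hochberg adjustment over 13714 tested genes (q times rank over p ran from 13701.2 to 13714.1 over the listed genes), so the table holds 14.2% of the genes the authors tested and ends where the p-value reaches 0.05. Genes outside it were either not tested or had a larger p-value, and no value of theirs was used. This filter removes small ratios: among genes with a mean of at least 1 FPKM the smallest absolute log2 ratio was 0.23. A median over listed genes therefore describes those genes, and it overstates the change of a pathway with members outside the table. The smallest p-value was 5e-05, shared by 385 genes. In 5 genes 1 library was listed at 0, and the authors' log2 value was then not a finite number. A spreadsheet had turned 1 gene name into a date. Of the names, 1734 were current symbols, 149 were older names and 64 were in neither reference table. Loci on alternative haplotypes or unplaced contigs numbered 20, and 30 genes shared their locus with another listed gene. Locus starts in the file count from 0 and were converted, because the locus length then equalled the reference gene length for 79 of 1725 genes compared, against 28 otherwise. Positions are in hg19 and give the span the authors' software reported, which can include overlapping genes.

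The ratio used was log2((FPKM in ebastine + 1)/(FPKM in vehicle + 1)), with a pseudocount of 1 FPKM, which understates the change of low genes. Counts of genes cover the 1768 genes with a mean FPKM of at least 1 over both libraries, and a gene was counted as higher or lower at a ratio of 2-fold or more. Sequencing depth is unknown, since the file gives no counts and only 3 genes had a mean under 0.3 FPKM from which a step of 1 read could be sought; no counting interval can be given.

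Before the data were examined, 35 gene lists were fixed. For each list with at least 5 listed members at a mean FPKM of at least 1 (14 lists), the median log2 ratio was placed among 10000 random lists of the same size drawn from the listed genes and matched on mean FPKM in 20 bins. A list was said to stand apart at a percentile of at most 1 or at least 99. The comparison had been planned on a table of all genes; drawn from the filtered table, it sets a list only against other genes past the authors' p-value limit. The comparison describes the 2 libraries, since genes are not replicates. The 1768 listed genes with a mean of at least 1 FPKM had a median log2 ratio of -0.32. A percentile is therefore set against random lists centred below 0, and a list can have every member lower without standing apart. Within lists, members at least 1.5-fold higher or lower were counted. List members were matched by symbol and by older names. Genes named in the text were chosen by a rule fixed at the same time. It took EZH2, EED, SUZ12 and EZH1, the 15 largest and 15 smallest log2 ratios among genes with a gene symbol and a mean of at least 5 FPKM (genes with a longest reference transcript under 200 bases left out), up to 4 members of each described list in the direction of its median, and up to 2 members against it. Other genes named are marked as chosen after their values were seen.

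The method was tested on simulated data made from the 1768 genes. Of 200 simulated lists of 20 genes with shuffled ratios, 3% stood apart, and of 200 lists whose members were all made higher, 92% stood apart above. Of 200 genes changed 3-fold, 94.5% passed the 2-fold limit. This checks the arithmetic and the pseudocount only and says nothing about the error of the 2-fold counts, since no spread between replicates exists to simulate. Alternatives covered the pseudocount, the filter on low values, the fold limit, 3 rescalings of the libraries (centring on the median of genes with a mean of at least 10 FPKM, upper quartile, and an equal sum of FPKM over the table, 1000000 in each library) and the settings of the random lists; leaving out a replicate was not possible. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Transcript length and GC content came from GENCODE transcripts of a newer build and were joined by gene name only.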

Results

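The transcriptome of C4-2 prostate cancer cells was compared between 1 library from vehicle-treated cells and 1 library from ebastine-treated cells. The series title names the histone H3K27 methyltransferase EZH2 as the target of the drug, so the comparison asks which transcripts differ in ebastine-treated cells and where EZH2 lies among them. The table held FPKM values of 1947 genes that the authors' Cuffdiff test separated at a p-value under 0.05, out of 13714 tested. The median FPKM of these genes was 10.5 in the vehicle library and 9.49 in the ebastine library. There were no replicates, the depth is unknown, and every ratio below is a difference between these 2 libraries without an error.

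Genes of cell division were lower and genes of sterol synthesis were higher in the ebastine library. Of the 1768 genes with a mean of at least 1 FPKM, 32 were at least 2-fold higher and 86 were at least 2-fold lower with ebastine. In the authors' deposited table, 304 genes were higher and 495 lower at a q-value under 0.05. Among genes with a mean of at least 5 FPKM, the lysosomal and melanosomal glycoprotein GPNMB (chromosome 7, 23286316 to 23314729) stood at 3.004 FPKM with vehicle and 24.9 FPKM with ebastine, a 6.48-fold ratio. The iron-siderophore binding protein LCN2 was 4.84-fold higher (1.61 against 11.6 FPKM), and the ubiquitin ligase NEDD4L (chromosome 18, 55711610 to 56068772) was 3.30-fold higher (44.6 against 149 FPKM). The ferritin heavy chain FTH1, which has many processed pseudogenes, went from 2301 to 5731 FPKM. The calcium-binding protein S100P was 2.13-fold higher, FGF13 2.12-fold and CCDC64 2.08-fold. The trypsinogen gene PRSS1 was 2.58-fold higher, but its reported locus spans 499 kb and can include other genes. LENEP had the highest ratio among these genes, 14.6-fold, from 0.183 to 16.3 FPKM, yet its q-value in the authors' deposited table was 0.305.

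The lowest ratios belonged to the securin gene PTTG1 (chromosome 5, 159848865 to 159855746), which stood at 220.3 FPKM with vehicle and 62.8 FPKM with ebastine. The pepsinogen PGC was 3.34-fold lower (39.2 against 11.02 FPKM), PHGR1 3.09-fold lower and the secreted protease inhibitor SLPI 2.81-fold lower (135 against 47.5 FPKM). ODC1, the rate-limiting enzyme of polyamine synthesis, went from 944 to 355 FPKM, a 2.65-fold difference. The DNA helicase PIF1 was 2.73-fold lower, the membrane protein TM4SF1 2.70-fold, PHLDA1 2.62-fold and the neuropeptide gene NMU 2.60-fold. The split into higher and lower genes depended on the scaling of the libraries. Centring on the median ratio of the listed genes with a mean of at least 10 FPKM (centring below), which multiplies the ebastine values by 1.27 (0.35 on the log2 scale), gave 121 higher and 24 lower genes, and an upper quartile rescaling (0.20 on the log2 scale) gave 72 and 45. Both were computed on the filtered table.

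**Figure D1:**
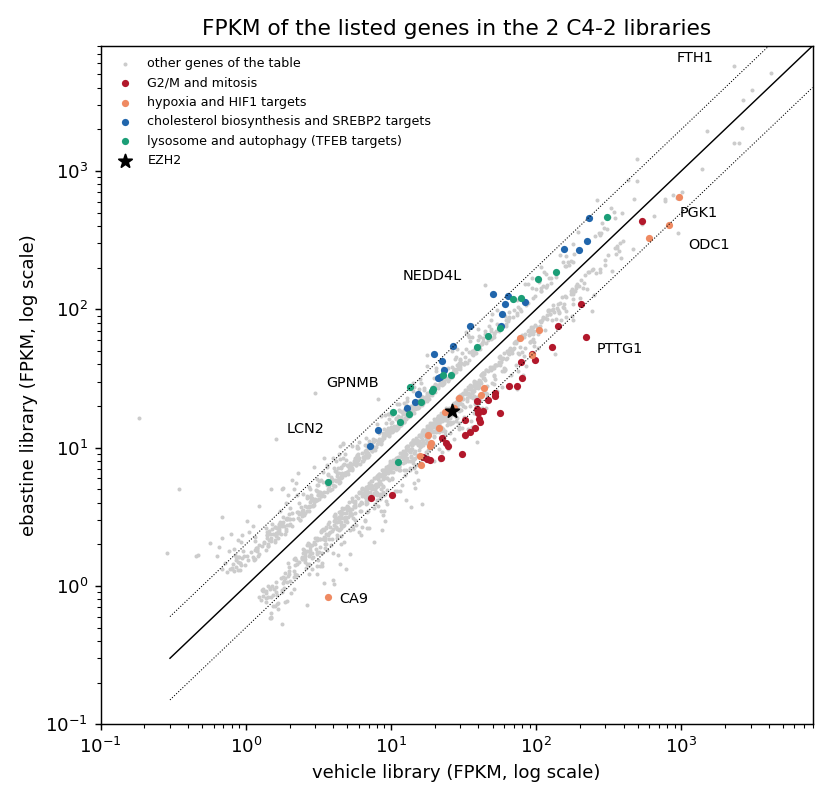
FPKM of each listed gene with a mean of at least 1 FPKM in the vehicle library (horizontal, log scale) and the ebastine library (vertical, log scale); the solid line marks equal values and the dotted lines 2-fold ratios. The empty band around the solid line is the authors' p-value filter, members of the mitosis list lie below the solid line, members of the cholesterol list lie above it, and EZH2 (star) lies at 26.2 and 18.4 FPKM.

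Mitotic genes were lower together in the ebastine library. All 35 members of the G2/M and mitosis list were in the table, against 14.2% of all tested genes, and all 35 were lower with ebastine, 34 of them by at least 1.5-fold. Their median log2 ratio was -1.11, a 2.15-fold difference, and 0 of 10000 random lists had a median as low. CENPE, a kinetochore motor, and HMMR, a spindle protein, were 3.21-fold and 3.04-fold lower, although the q-value of CENPE was 0.306 in the authors' deposited table. The mitotic kinase PLK1 went from 37.9 to 13.9 FPKM, and DLGAP5, CCNB2 and KIF20A were 2.60-fold, 2.59-fold and 2.57-fold lower. The smallest difference was that of CKS2, at 536 and 438 FPKM, and it was the member whose direction turned after centring, with 34 of 35 still lower and a median of -0.78; CKS2 was chosen after its values were seen. The proliferation marker MKI67, also chosen after its values were seen, stood at 22.4 and 11.6 FPKM.

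Genes of DNA replication and repair were lower by smaller amounts. Of 36 replication genes 21 were listed, all 21 were lower, and 7 were lower by at least 1.5-fold; their median log2 ratio was -0.51, and 57 of 10000 random lists had a median as low. Thymidine kinase TK1 went from 161 to 87.6 FPKM, thymidylate synthase TYMS from 72.3 to 39.4 FPKM, the ribonucleotide reductase subunit RRM2 from 60.2 to 37.4 FPKM and the clamp loader subunit RFC3 from 84.2 to 52.7 FPKM. The list no longer stood apart with pseudocounts of 0.1 and 5 or with equal sums (percentiles 1.21, 1.20 and 1.21). After centring, 19 of the 21 were still lower, with a median of -0.17. Of 25 homologous recombination and DNA damage genes 16 were listed, 15 lower and 1 higher, with a median of -0.54 at percentile 1.05, just outside the limit of 1; the list stood apart under 3 other settings. FANCD2, FANCI, BRCA2 and CHEK2 were 1.68-fold, 1.63-fold, 1.62-fold and 1.58-fold lower, and BARD1 was 1.33-fold higher.

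Genes of cholesterol synthesis were higher together. Of 26 members 22 were listed and all 22 were higher with ebastine, 13 of them by at least 1.5-fold. The median log2 ratio was 0.66, a 1.58-fold difference, and 0 of 10000 random lists had a median as high. TM7SF2, a sterol reductase, went from 50.1 to 127.9 FPKM. HMGCS1, which makes the HMG-CoA of the mevalonate pathway, went from 19.9 to 47.8 FPKM (chromosome 5, 43287572 to 43313614). The sterol methyl oxidase MSMO1 and the squalene synthase FDFT1 were 2.10-fold and 1.99-fold higher. Of 16 fatty acid synthesis genes 6 were listed and all 6 were higher, with a median of 0.75 that 5 of 10000 random lists reached, and of 0 with unlisted members counted at 0. The desaturase SCD went from 261 to 616 FPKM, and ACSS2, LPIN1 and ME1 were 1.79-fold, 1.78-fold and 1.59-fold higher.

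Lysosomal genes were also higher. Of 35 lysosome and autophagy genes 19 were listed, 18 higher and 1 lower, with 6 higher by at least 1.5-fold. The median log2 ratio was 0.44, which 9 of 10000 random lists reached. The sialidase NEU1 went from 13.5 to 27.2 FPKM, the lysosomal cholesterol transporter NPC1 from 10.2 to 18.2 FPKM, the autophagy receptor SQSTM1 from 69.5 to 118.9 FPKM and the protease cathepsin D (CTSD) from 103 to 166 FPKM. ATG9B was 1.36-fold lower. The locus of NEU1 lies on an alternative haplotype of chromosome 6, where reads can be split between copies. The reported locus of CTSD spans 295 kb and can include other genes. Of 21 NRF2 targets 10 were listed, 7 higher and 3 lower, with a median of 0.52 at percentile 99.8. It did not stand apart with a pseudocount of 5 (percentile 98.5) or a minimum mean of 5 FPKM (97.8), and its median was 0 with unlisted members counted at 0. The higher members included both ferritin chains, FTH1 at 2.49-fold and FTL at 1.65-fold, with AKR1C1 at 1.83-fold from only 0.454 FPKM, and the classical NRF2 targets HMOX1 and SLC7A11 were 1.39-fold and 1.32-fold lower.

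Genes induced by hypoxia and genes of glycolysis were lower. Of 25 hypoxia genes 20 were listed; the 18 with a mean of at least 1 FPKM were all lower, 11 by at least 1.5-fold, with a median log2 ratio of -0.72 that 0 of 10000 random lists reached. After centring, 17 of the 18 were still lower, with a median of -0.40. Carbonic anhydrase CA9 went from 3.70 to 0.827 FPKM, ANKRD37 from 16.2 to 7.48 FPKM, and NDRG1 from 93.3 to 46.6 FPKM. CA9 is a low gene and did not have a q-value under 0.05 in the authors' deposited table. The glycolytic enzyme PGK1 went from 818 to 408 FPKM. Of 19 glycolysis genes 13 were listed, of which 4, PGK1 and HK2 among them, are also on the hypoxia list, so the lists are not independent. Of the 13, 12 were lower and 1 was higher, with a median of -0.52 that 64 of 10000 random lists reached. The list lay at percentile 1.09 with 5 expression bins, where it did not stand apart, and its median was -0.18 after centring. ENO2, the lactate transporter SLC16A3 and hexokinase HK2 were 1.64-fold, 1.55-fold and 1.51-fold lower, and ALDOC was 1.41-fold higher.

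**Figure D2:**
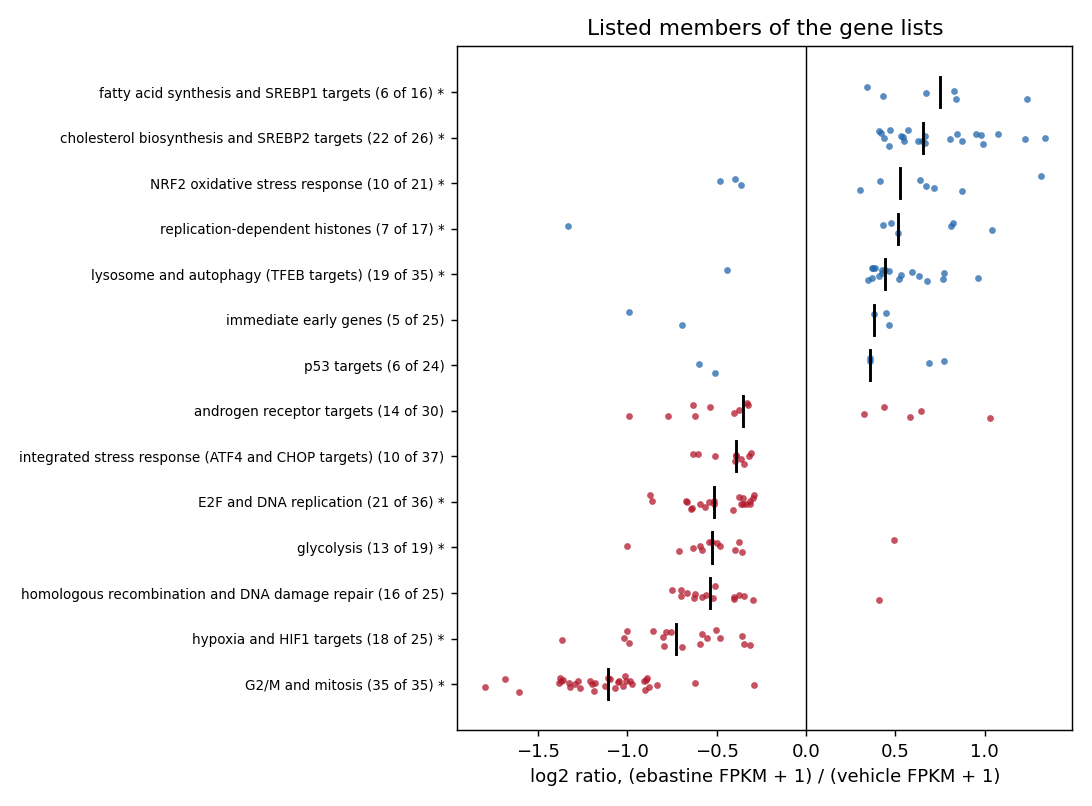
Log2 ratio of ebastine over vehicle (horizontal) for each listed member, as a point, of the 14 gene lists with at least 5 listed members; vertical bars are medians, red and blue mark lists with a median below and above 0, and asterisks mark lists that stood apart from random lists. Numbers in brackets give members shown and list size, and the mitosis list, at a median of -1.11, and the cholesterol list, at 0.66, do not overlap.

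EZH2 was lower in the ebastine library by a modest amount. EZH2 (chromosome 7, 148504464 to 148581441) stood at 26.2 FPKM with vehicle and 18.4 FPKM with ebastine, a 1.40-fold difference and a log2 ratio of -0.48. The authors' deposited table gives it a q-value of 0.0278. Among the 500 listed genes nearest to it in mean FPKM the ratio lay at percentile 31.4. The ratio ran from -0.50 to -0.15 over the alternatives tried. A change of pseudocount cannot turn its sign, and equal sums rescale ebastine against vehicle by only 1.001. Upper quartile rescaling and centring, which could have turned it, left it at -0.29 and -0.15. Of 13 PRC2 genes, PHF19, an accessory subunit, was the only other one listed, and it was 1.48-fold lower (9.44 against 6.06 FPKM); EED, SUZ12 and EZH1 are not among the listed genes and no value is given. Of 20 PRC1 genes RYBP was listed, 1.26-fold lower, and of 13 H3K27 demethylases and H3K4 methyltransferases the demethylase KDM6B was listed, 1.23-fold higher. Of 25 genes reported as repressed by EZH2 in cancer cells 4 were listed, or 16%, beside 14.2% of all tested genes. The 16% counts all 25 members, and how many of them the authors tested is unknown, so the shares cannot be compared directly. The cyclin-dependent kinase inhibitor CDKN1A was 1.61-fold higher (27.8 against 45.5 FPKM) and IGFBP3 1.25-fold higher, while CDKN1C was 1.30-fold lower and E2F2 1.23-fold lower. In the authors' deposited table CDKN1A had a q-value under 0.05, but PHF19, RYBP, KDM6B, IGFBP3, CDKN1C and E2F2 did not.

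Androgen receptor targets went both ways. Of 30 targets 14 were listed, 9 lower and 5 higher, with a median of -0.35 at percentile 28.8, which did not stand apart; after centring 8 were lower and 6 higher, with a median of -0.01. KLK3, which encodes prostate-specific antigen, went from 2476 to 1599 FPKM, KLK2 from 465 to 272 FPKM and FKBP5 from 90.5 to 58.4 FPKM, whereas the acid phosphatase gene ACPP was 2.04-fold higher and STEAP2 1.56-fold higher. Of 24 p53 targets 6 were listed, with TP53INP1 1.71-fold, SESN1 1.28-fold and KIAA0247 1.28-fold higher beside CDKN1A, and with DDB2 1.51-fold and GDF15 1.42-fold lower; the list lay at percentile 87.8. Of 37 integrated stress response genes 11 were listed, and the 10 with a mean of at least 1 FPKM were all lower, 8 of them after centring. Their median was -0.39 at percentile 19.5, where the random lists had a median of -0.31. FGF21 was 1.55-fold lower from 1.46 FPKM and MTHFD2 1.52-fold lower.

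Other lists held few listed members. Most genes named in this paragraph did not have a q-value under 0.05 in the authors' deposited table. The exceptions were KLF4, DUSP4, JUNB, ERO1L, PMAIP1, ISG15, MT1X, MT2A, ODC1, LOX and ENO2. Of 25 immediate early genes 5 were listed, at percentile 89.0; KLF4 was 1.99-fold and DUSP4 1.62-fold lower, and JUNB, DUSP1 and DUSP5 were 1.38-fold, 1.36-fold and 1.30-fold higher. Of 27 unfolded protein response genes 3 were listed, ERO1L, HSP90B1 and XBP1, at ratios of -0.69, -0.34 and -0.29 on the log2 scale, and after centring HSP90B1 and XBP1 lay at 0.0028 and 0.0542, on the other side of 0. Of 23 apoptosis genes PMAIP1 was 1.45-fold lower and BMF 1.21-fold higher. Listed members numbered 2 of 31 interferon genes (HLA-B and ISG15, 1.57-fold and 1.48-fold higher), 2 of 22 inflammatory genes (RELB at 0.539 and 1.04 FPKM, chosen after its values were seen, and LIF, 1.21-fold higher), 3 of 11 metallothionein and zinc genes (MT1X 1.45-fold and MT2A 1.39-fold lower, SLC30A1 1.25-fold higher) and 3 of 30 MYC and ribosome biogenesis genes (ODC1, RRS1 at 1.33-fold higher, and FBL at 1.26-fold lower but with a log2 ratio of 0.016 after centring). They numbered 2 of 32 ribosomal protein genes (RPL38 1.25-fold and RPLP1 1.24-fold higher), 2 of 20 epithelial genes (DSP 1.32-fold lower, ELF3 1.31-fold higher), 3 of 20 mesenchymal genes (LOX 2.17-fold and VIM 1.24-fold lower, FN1 1.40-fold higher) and 2 of 20 neuroendocrine genes (ENO2 lower, CALCA 1.41-fold higher). The reported locus of HLA-B lies on an alternative haplotype of chromosome 6 and spans 88.7 kb, so its value can include other genes. The list for histamine receptors and ebastine metabolism also holds other genes. Of its 14 members 3 were listed, none of them a histamine receptor, and all 3 were higher. The sterol isomerase EBP, also on the cholesterol list, was at 1.34-fold, the ebastine hydroxylase CYP2J2 at 1.29-fold and the potassium channel KCNH2 at 1.21-fold. None of the 17 heat shock, 27 nuclear oxidative phosphorylation or 13 mitochondrially encoded genes on the lists was in the table. Of the markers of other cell types, 0 of 15 basal and squamous, 0 of 16 fibroblast and endothelial and 1 of 18 leukocyte markers were listed; the last was CD4, chosen after its values were seen, at 0.400 and 0.693 FPKM.

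Most listed replication-dependent histone genes were higher in the ebastine library. Transcripts of this class largely lack a poly(A) tail and polyadenylated RNA was sequenced, so the form of the transcripts measured is not known. Of 17 replication-dependent histone genes 7 were listed, 6 higher and 1 lower, with a median of 0.52 that 52 of 10000 random lists reached, and of 0 with unlisted members counted at 0. HIST3H2A went from 32.7 to 68.4 FPKM, HIST2H2BE, HIST1H4H and HIST1H2AC were 1.77-fold, 1.75-fold and 1.43-fold higher, and HIST2H2AC was 2.51-fold lower. These genes have near-identical copies, so their reads can be split. Reported loci spanned 15.0 kb for HIST1H2AC and 4.48 kb for HIST1H4H. They spanned 0.496 kb for HIST3H2A, also higher, and 0.437 kb for HIST2H2AC, which was lower. RPPH1, the RNA of ribonuclease P, was 2.11-fold higher (17.8 against 38.6 FPKM). The nuclear RNA MALAT1, chosen after its values were seen, went from 429.9 to 864.8 FPKM.

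Of the 14 lists with at least 5 listed members, 9 stood apart. With the genes limited to those with a q-value under 0.05 in the authors' deposited table, 9 of the 14 lists kept at least 5 members, and 3 of those 9 stood apart: mitosis, hypoxia and cholesterol synthesis. The fatty acid and histone lists had 4 and 2 members left and could not be placed. The replication, glycolysis, lysosome and NRF2 lists lay at percentiles 21.2, 24.1, 98.2 and 97.3. Their medians, -0.64, -0.56, 0.61 and 0.69, lay farther from 0 than before. A stricter limit tends to leave out smaller ratios, so this does not show a stronger difference.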

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

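The limit to genes with a q-value under 0.05, the correction for GC content and length and the medians with unlisted members at 0 were chosen after seeing the data. The count of 32 genes at least 2-fold higher became 56 and 12 with pseudocounts of 0.1 and 5, 21 with a minimum mean of 5 FPKM, 121 after centring on the median, 72 after upper quartile rescaling, 57 after rescaling to equal sums and 171 at a limit of 1.5-fold. The count of 86 genes at least 2-fold lower became 30 with a pseudocount of 5, 24 after centring, 45 after upper quartile rescaling and 328 at 1.5-fold; with a pseudocount of 0.1 and with equal sums it was 126. Apart from the limits that are part of a setting itself, the cause was not tested. Equal sums of 1000000 raise all values, so the pseudocount weighs less. The centring and upper quartile settings were computed on a table already filtered by p-value, so they need not reflect the whole libraries. Under centring the log2 ratios of 5 named genes changed sign, to 0.055 for CKS2, 0.016 for FBL, 0.0028 for HSP90B1, 0.0047 for TUBG1 and 0.0542 for XBP1, because one factor raises every ratio. The number of lists that stood apart was 9 and ran from 7 to 10 over the settings set in advance; among genes with a q-value under 0.05 it was 3 of the 9 lists that kept at least 5 members. There the other 5 lists, with the fatty acid and histone lists among them, had too few members to be placed. The lists that no longer stood apart lay at percentiles 21.2 (replication), 24.1 (glycolysis), 98.2 (lysosome) and 97.3 (NRF2). Their medians were farther from 0 (-0.64, -0.56, 0.61 and 0.69 in that order), but a stricter limit tends to leave out smaller ratios. The mitosis, cholesterol, hypoxia, fatty acid, lysosome and histone lists stood apart under each setting set in advance. Some of these settings could hardly have changed that. Centring and upper quartile rescaling multiply every ebastine value by the same factor, which moves a list and its random lists nearly alike. The wider percentile limits can only add lists, and equal sums nearly repeat the pseudocount of 0.1. The replication list (median -0.51) did not stand apart with pseudocounts of 0.1 (-0.52) and 5 (-0.41) and with equal sums (-0.52). The NRF2 list (0.52) did not with a pseudocount of 5 (0.34) and a minimum mean of 5 FPKM (0.41), nor the glycolysis list with 5 expression bins, which leave its median as it was. The homologous recombination list stood apart without a filter, with 5 expression bins and with the wider percentile limits. The cause was not tested. With members outside the table counted at a log2 ratio of 0, the medians were -1.11 for mitosis, -0.31 for replication, 0.60 for cholesterol synthesis, 0.35 for lysosome, -0.55 for hypoxia and -0.40 for glycolysis, but 0 for the fatty acid, NRF2 and histone lists, which have most members outside the table. Summing or choosing among rows that share a symbol changed nothing, because 0 rows did. Depth is unknown, and with 1 library per group no replicate could be left out.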

Other observations

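The lists in this part were written after the table was seen, and so were FOLH1, the comparison of EZH2 with the replication genes and the test of a single scaling factor. Beyond the mitosis list, 33 of 40 genes of the kinetochore, centromere and condensin were in the table and all 33 were lower with ebastine, with a median log2 ratio of -0.78; after centring 31 of the 33 were still lower, with a median of -0.46. NUF2 went from 35.7 to 15.5 FPKM and CASC5, CENPH and SGOL2 were 2.10-fold, 2.08-fold and 2.08-fold lower. Of 13 tubulin and stathmin genes 4 were listed; the microtubule destabiliser STMN1 went from 178 to 83.8 FPKM and TUBA1B from 333 to 189.7 FPKM (1.75-fold lower), TUBG1 was 1.26-fold lower (0.0047 on the log2 scale after centring) and TUBB4A was 1.36-fold higher.

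Of 19 iron handling genes 7 were listed, 6 higher and 1 lower, with a median of 0.72; FTH1, FTL and HMOX1 are also on the NRF2 list, and the list was prompted by its highest members. The transferrin receptor TFRC went from 87.6 to 152 FPKM, beside FTH1, FTL and LCN2, while HMOX1 was lower. Of 16 vacuolar ATPase subunits 7 were listed and all 7 were higher, with a median of 0.43 at percentile 96.9, so the list did not stand apart; 3 of the 7 are also on the lysosome list. ATP6V0A1 went from 8.31 to 13.0 FPKM and ATP6AP1 was 1.42-fold higher. Of 7 BMP-responsive genes ID3 and ID1 were listed, 2.21-fold and 1.92-fold higher from levels of 2.07 and 2.16 FPKM. The prostate membrane antigen gene FOLH1 went from 495 to 840.4 FPKM.

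The lower mitosis genes and the higher cholesterol genes were set against technical explanations. GC content and transcript length explained 9.08% of the variance of the log2 ratio together with mean FPKM, and after their removal the median of the mitosis list was -1.05, that of the cholesterol list 0.73 and that of the hypoxia list -0.75, so these properties do not account for the whole of any of the 3 lists. A single scaling factor between the libraries is argued against as the cause of both lists, because their medians lie 1.76 apart on the log2 scale while their interquartile ranges together span 0.72. A difference between the 2 cultures other than the drug, such as cell density or time in culture, may account for either list and cannot be told apart from the treatment, since each group has 1 library. The ebastine treatment itself stays open, and no biological explanation was tested.

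A hypothesis for the lower EZH2 transcript is that EZH2 follows the S-phase and replication genes, among which it is commonly counted as an E2F target. Its log2 ratio of -0.48 lay at percentile 52.4 of the 21 listed replication genes, 11 of which were lower by more than EZH2. The range from the 10th to the 90th percentile of these genes, -0.67 to -0.31, also held 684 of all 1007 lower listed genes (67.9%), so a place inside it decides nothing, and the hypothesis stays open. A direct effect of the drug on EZH2 transcription was not tested.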
